A study of Mus musculus with 4 samples.

How the data were processed

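Polyadenylated RNA of cultured mouse astrocytes was sequenced in 4 libraries, 2 of the wild-type group AC and 2 of the group TRP. Per the labels' protocols, the cells grew in serum-containing medium, RNA was extracted from cell pellets, libraries were made with a stranded mRNA kit, and sequencing ran on an Illumina NextSeq instrument. Per the submitters' processing notes, GSNAP and the genome build mm9 were used, with no version or role given. The counting tool, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart with certainty, and neither can reads of near-identical gene copies.

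The deposited table holds whole-number counts per gene for 23893 gene rows, with 1 column per library and no normalization by the authors. Column names matched the sample titles. Column totals were 36125089 for AC 1, 34097156 for AC 2, 56216491 for TRP 1 and 68254813 for TRP 2. The 10 most abundant genes took between 3.19% and 3.53% of a library. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to 0.0792 CPM in AC 1, 0.0848 in AC 2, 0.0556 in TRP 1 and 0.046 in TRP 2. Such floors and the 95% intervals of ratios with few counts cover counting error only. A total of 27 rows carry date-like names instead of gene symbols, with 2 names occurring more than once. They were kept in the library sizes and tests and are not named. No gene of the mitochondrial genome is in the table.

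Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (16428 genes), libraries were scaled by TMM, and the quasi-likelihood F-test compared TRP with AC with group as the only term and 2 residual degrees of freedom. The p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. A further test (glmTreat) asked for a change beyond 1.5-fold. CPM values (counts scaled to the TMM-adjusted library size) were computed here from the deposited counts. Standard errors were taken from the log2 fold change and the F statistic. A fold change of a gene without counts in a group is given as a bound, computed against 3 counts per library, and a gene with 1 to 3 counts in a group is given as a ratio with its counting interval.

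A total of 26 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. The lists, the tests and the rule for named genes were chosen before the data were examined. The rule took 14 fixed genes. It added the 12 largest rises and the 12 largest falls among genes that passed the test, had groups that did not overlap and reached a mean of 20 CPM in the higher group. From each list it took up to 2 members with the smallest p among those that rose and up to 2 among those that fell, or the 2 with the smallest p where none passed. Eligible were 1245 genes as rises and 748 as falls. Until 12 genes were named in each direction, 1 predicted gene was passed over among the rises and 0 among the falls.

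The labels do not say that the 2 libraries of a group came from separate cultures or animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical in AC. In TRP, a biological coefficient of variation of 0.597 and 232 genes at least 8-fold apart argue against a technical spread alone. Camera with the preset correlation takes genes rather than libraries as units, so its p-values do not measure that spread. Genotype and passage number change together, so no term for passage could be fitted. Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma voom, a replicate block, each library left out, a prior count of 0.5, a threshold of 0.01 and other gene list tests. Limma voom with a variance factor for each group was added after the data were seen. With fewer than 3 libraries in a group, no count over other splits of the samples was made.

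The procedure was tested on simulated counts with the means and library sizes of the real samples. With an equal spread in both groups, 73 of 199 changed genes were called, with 1 false call among the 16135 genes tested. Recovery was 4.55% for genes changed 2-fold, 20.9% for 4-fold and 84.8% for 8-fold. With the spread of each group taken from the data, 0 of 198 changed genes were called by edgeR and 0 by limma voom, and 1378 genes had an unadjusted p under 0.05. In the matching simulation without changed genes, edgeR and limma voom each called 0 of 16198 genes, and 1241 had an unadjusted p under 0.05. With an equal spread and no changed genes, 832 of 16167 had one. Numbers of genes at an unadjusted edgeR p under 0.05 are therefore likely too high where the groups differ in spread. A simulated gene list that was moved had a camera p of 4.41e-07, and 3 of 100 random lists had a p under 0.05. All simulated genes of a group shared the same spread, few genes were changed, and none by more than 8-fold. Spread in real genes is not the same for all. The recovery rates therefore do not carry over to the real data, where edgeR called 3348 genes. Simulated genes were also drawn independently of each other. The simulation therefore does not check the preset correlation for real lists, whose members may vary together.

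Positions of genes were not printed, because the annotation at hand is of another build (RefSeq GRCm38.p6) than the one in the processing notes. It was used only to tell which genes share a chromosome or lie next to each other, and 93.3% of the symbols in the table were found in it on the autosomes or X. GC content and transcript length came from the longest transcript of each symbol in GENCODE vM21. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for these steps and the plots.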

Results

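Gene expression was measured by RNA sequencing in cultured astrocytes of C57BL6 mice. The AC group held 2 libraries of wild-type cells at passage 2. The TRP group held 2 libraries of cells at passages 12 to 15 whose label names a truncated SV40 T antigen, a mutant KRas (G12D) and a Pten deletion. T antigen binds proteins of the retinoblastoma family, KRas is a GTPase upstream of the MAPK cascade, and Pten opposes PI3K signalling. Libraries held between 34097156 and 68254813 counts, and the TRP libraries were the deeper ones. The comparison of TRP with AC addresses what changes in astrocytes that carry mutations in core glioblastoma pathways. Passage number changes with genotype and the make-up of the cultures may differ, so no difference can be assigned to the mutations alone. The series title refers to loss of differentiation, stem cells, radiation and temozolomide.

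Among the genes that the genotype names, Kras stood at 123 ± 0.894 CPM (SD, n = 2) in AC and 147 ± 13.3 CPM in TRP, with a log2 fold change of 0.26 ± 0.11 (SE) and an edgeR adjusted p of 0.184. Pten stood at 175 ± 8.20 CPM in AC and 174 ± 18.7 CPM in TRP, a log2 fold change of -0.01 ± 0.13 with an edgeR adjusted p of 0.967. The label does not say which part of Pten was deleted, and counts over the whole gene cannot show the loss of an exon, so these values check nothing about the label. T antigen has no row in the mouse gene table. Rb1 had a log2 fold change of -0.19 (edgeR adjusted p = 0.67). Its relative Rbl1 was higher in TRP, at 0.75 (edgeR adjusted p = 0.0368), and Rbl2 was lower, at -0.53 (edgeR adjusted p = 0.0447). Trp53 had a log2 fold change of 0.94 ± 0.22 that did not pass the test (edgeR adjusted p = 0.0641).

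Cdkn2a, which encodes the cell cycle inhibitors p16 and Arf, differed widely between TRP 1 and TRP 2. It had 163 and 257 counts in AC 1 and AC 2, 15949 in TRP 1 and 13 in TRP 2, so its log2 fold change of 4.68 ± 3.01 did not pass the test (edgeR adjusted p = 0.318). Without TRP 1 the log2 fold change was -4.84. Olig2, a transcription factor of oligodendrocyte precursors and glioma cells, had 7298 and 7964 counts in AC, 8 in TRP 1 and 8563 in TRP 2. Scaled to library size, it stood at 193 and 225 CPM in AC, 0.148 in TRP 1 and 131 in TRP 2. The log2 fold change of Olig2 was -1.67 (edgeR adjusted p = 0.646). Its log2 fold change was -10.43 without TRP 2 and -0.67 without TRP 1.

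**Figure D1:**
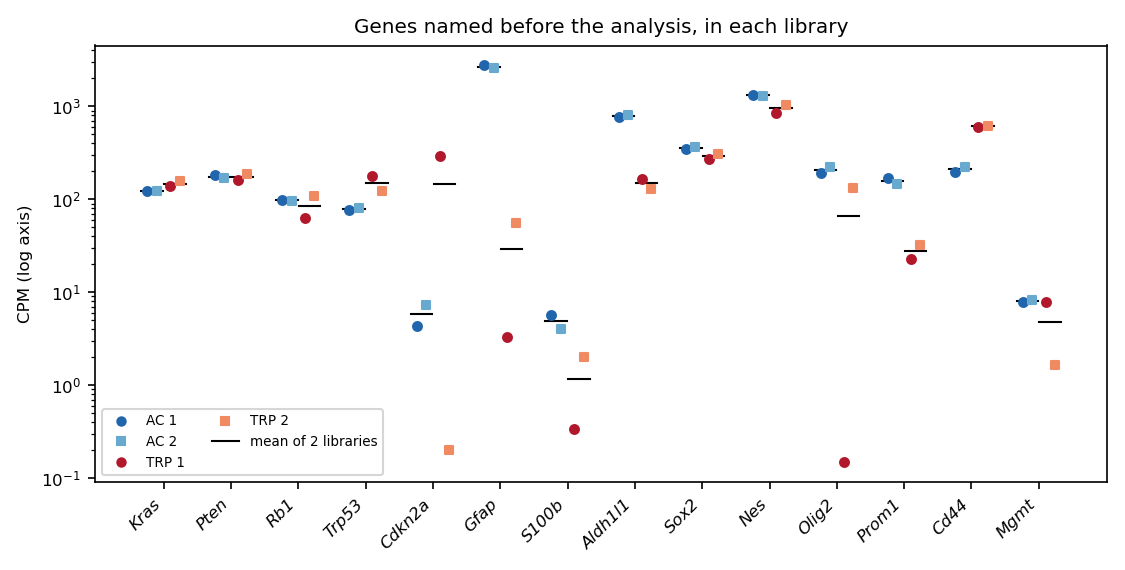
Normalised expression of the 14 genes fixed before the data were examined, in CPM on a log axis. Each point is 1 library (AC blue, TRP red or orange) and black lines are means of 2 libraries. Cdkn2a, Olig2 and Gfap lie far apart between TRP 1 and TRP 2, while Aldh1l1, Prom1 and Cd44, the 3 genes shown with an edgeR adjusted p under 0.05, lie close together within each group.

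In total 3348 of the 16428 tested genes differed between TRP and AC by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 1371 were higher in TRP, with a median log2 fold change of 1.03, and 1977 were lower, with a median of -4.21 among fitted values. Of the lower genes, 413 had at most 1 count in each TRP library, whereas 12 of the higher genes had at most 1 count in each AC library. The test for a change beyond 1.5-fold called 348 genes higher and 1150 lower. The groups did not overlap in all 3348 called genes and in 73.9% of the tested genes. Chance gives 33.3% only if all libraries vary alike. The biological coefficient of variation was 0.0909 in AC and 0.597 in TRP, so 33.3% is not a fair reference here. Lower genes made up 59.1% of the calls, and 69.7% with upper quartile factors or 70.2% with library size alone. Those scalings moved the median of all genes from -0.005 to -0.131 and -0.128 on the log2 scale. Among called genes with a mean of 20 CPM or more in the higher group, 1245 were higher in TRP and 748 lower. The majority of lower genes therefore did not hold among more abundant genes.

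The number of calls depended on single libraries, since the spread within AC and TRP was pooled. Without AC 1 or without AC 2, edgeR called 0 genes in either direction, although 2251 and 2412 genes had an unadjusted p under 0.05, limma voom called 0 in both cases, and DESeq2 called 1203 and 1367. Without TRP 1 edgeR called 10861 genes and without TRP 2 it called 11670, each including all 3348.

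The 12 largest rises by the fixed rule were in Tmem171, Cbr2, S100a4, Fam110c, Syne3, Unc5b, Rgs8, Gbp9, Trib3, Chst1, Twist1 and Itpr3. Tmem171, which encodes a membrane protein, rose from 0.195 ± 0.164 CPM (SD, n = 2) to 38.9 ± 5.89 CPM, a log2 fold change of 7.64 ± 0.76. S100a4, a calcium-binding protein of motile and mesenchymal cells, rose from 7.60 ± 1.08 to 381 ± 172 CPM. The netrin receptor gene Unc5b rose from 16.2 ± 0.631 to 417 ± 200 CPM, and Trib3, a pseudokinase induced by stress, from 1.53 ± 0.517 to 28.3 ± 10.96 CPM. Log2 fold changes of the 12 genes lay between 4.04 (Itpr3) and 7.64, with edgeR adjusted p between 0.0217 and 0.0485. The call of Itpr3 ended under each other scaling and filter tried, and those of Cbr2, Gbp9 and Itpr3 ended with limma voom.

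The 12 largest falls were in Col22a1, Nudt11, Rian, Meg3, Fezf2, Aldh1a2, Kcne1l, Miat, Ntrk2, Sncaip, Ctss and B3gat1. Ntrk2, the receptor for brain-derived neurotrophic factor, fell from 1256 ± 79.7 CPM (SD, n = 2) in AC to 0.265 ± 0.297 CPM in TRP. Col22a1 was at least 987-fold lower, Nudt11 at least 636-fold, Fezf2 at least 499-fold and Aldh1a2 at least 415-fold, each with 0 counts in both TRP libraries. The non-coding RNAs Rian and Meg3, neighbours in an imprinted cluster, had 1 count each over both TRP libraries. Their ratios of AC to TRP were 14585 (95% counting interval 2617 to 576157) and 14327 (2571 to 565939). The ratio was 5431 (1503 to 44857) for the non-coding RNA Miat, 8832 (1585 to 348907) for Kcne1l, 4854 (1343 to 40088) for Sncaip, 5527 (991 to 218380) for the lysosomal protease gene Ctss and 4798 (861 to 189588) for B3gat1. The edgeR adjusted p of the 12 genes lay between 0.0166 and 0.0234.

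Astrocyte markers were lower in TRP. Of 20 measured members 9 fell, 0 rose and 11 did not pass, with 11 falls when adjusted over the list alone. The list had a median log2 fold change of -3.26 (-3.19 with genes without counts at their bound) and a camera adjusted p of 1.41e-06, against an adjusted p of 0.346 with an estimated correlation. The median was -2.85 without TRP 1 and -4.15 without TRP 2. Aqp4, the water channel of astrocyte endfeet, fell from 396 ± 43.8 CPM (SD, n = 2) to 1.55 ± 0.0423 CPM. Clu, a secreted chaperone, fell from 1079 ± 46.6 to 48.3 ± 16.7 CPM, and Aldh1l1, a folate enzyme used as an astrocyte marker, from 789 ± 30.2 to 149 ± 26.9 CPM with an edgeR adjusted p of 0.0217. Gfap, the intermediate filament of astrocytes, had 104872 and 91041 counts in AC, 176 in TRP 1 and 3594 in TRP 2, and did not pass (log2 fold change -6.52 ± 1.71, edgeR adjusted p = 0.0764). S100b had a log2 fold change of -2.04 with an edgeR adjusted p of 0.214.

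Markers of other cell types that a brain culture can hold were lower in TRP as well. Of 19 microglia and macrophage markers 16 fell and 3 did not pass, or 18 adjusted over the list alone, with a median log2 fold change of -6.79 (camera adjusted p = 2.07e-09, adjusted p = 0.346 with an estimated correlation). The fractalkine receptor gene Cx3cr1 fell from 37.1 ± 6.64 CPM (SD, n = 2) to 0.0677 ± 0.00904 CPM and the complement gene C1qc from 47.2 ± 9.53 to 0.414 ± 0.0434 CPM. Of 13 tested oligodendrocyte lineage markers 5 fell (8 over the list alone), among them Sox10 with 1342 and 826 counts in AC against 2 and 1 in TRP, a ratio of 1176 (402 to 5706), and Gpr17, with a ratio of 2952 (529 to 116645). Their median was -3.04 (camera adjusted p = 0.000186, adjusted p = 0.346 with an estimated correlation), or -2.47 without TRP 1 and -5.07 without TRP 2. Of 9 ependymal markers 7 fell (8 over the list alone), including the cilia genes Rsph4a and Dnah9, with a median of -4.49 (camera adjusted p = 5.12e-05, adjusted p = 0.346 with an estimated correlation), or -4.83 without TRP 1 and -6.85 without TRP 2.

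Of 14 pericyte and meningeal fibroblast markers 6 fell (7 over the list alone), among them Dcn and Aldh1a2. Their median was -3.82, or -3.69 with bounds (camera adjusted p = 0.00824, adjusted p = 0.447 with an estimated correlation). The matrix proteoglycan gene Dcn fell from 18.7 ± 8.98 CPM (SD, n = 2) to 0.0677 ± 0.00904 CPM. Of 9 endothelial markers 3 fell, with a median of -1.60 (camera adjusted p = 0.0415, adjusted p = 0.346 with an estimated correlation), among them the VEGF receptor gene Kdr, from 43.0 ± 4.46 to 3.12 ± 0.274 CPM, and Esam, at -3.75. Adjusted over the list alone the number was also 3. Of 13 neuron markers 3 fell, and 4 fell and 1 rose adjusted over the list alone, with a median of -2.67 (camera adjusted p = 0.0415, adjusted p = 0.346 with an estimated correlation). The synaptic gene Snap25 was at least 23.6-fold lower and Gad1 had a log2 fold change of -4.94. Of these calls, that on pericyte markers ended without TRP 2 (camera adjusted p = 0.123), that on neuron markers without AC 1 (0.0682) or TRP 2 (0.0796), and that on endothelial markers without AC 2 (0.0607), TRP 1 (0.117) or TRP 2 (0.104). The neuron and endothelial calls also ended with upper quartile factors, library size alone and the stricter filter, and the neuron call with DESeq2. Without TRP 2 the neuron median was -4.79, the endothelial one -3.70 and the pericyte one -4.61.

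**Figure D2:**
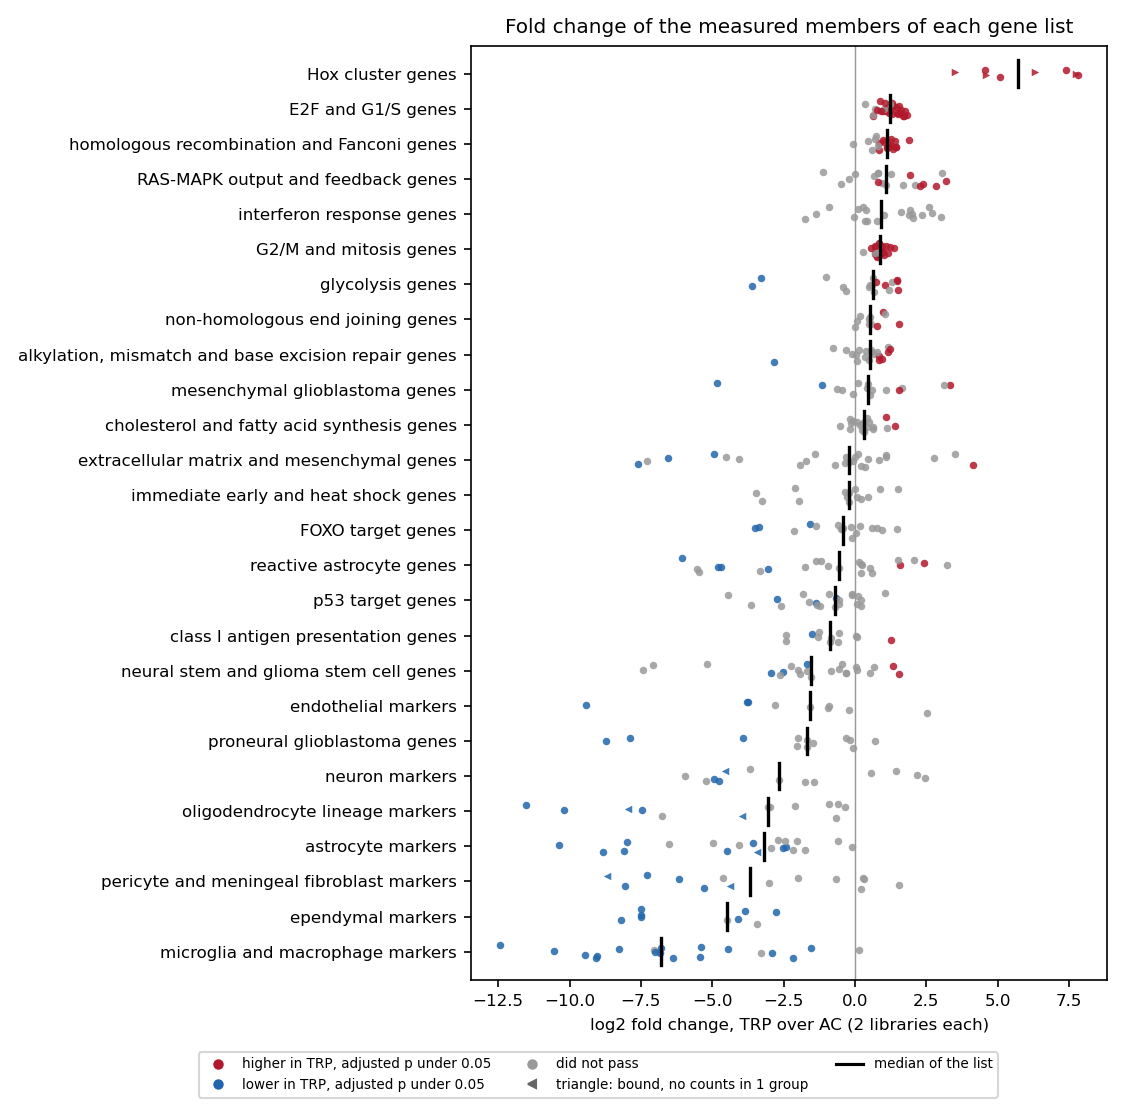
Log2 fold change of TRP over AC for each tested member of the 26 gene lists, with 1 point per gene. Points are red or blue where the edgeR adjusted p was under 0.05 and grey otherwise, triangles are bounds for genes without counts in a group, genes with 1 to 3 counts in a group stand at their count ratio, and black lines are medians with bounds. Medians range from -6.79 for microglia and macrophage markers to 5.70 for Hox cluster genes.

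Neural stem and glioma stem cell genes moved in both directions. Of 23 members 2 rose, 3 fell and 18 did not pass (2 and 4 over the list alone), and the list as a whole was not called, with a median log2 fold change of -1.55 and a camera adjusted p of 0.0646. The hyaluronan receptor gene Cd44 rose from 211 ± 20.9 CPM (SD, n = 2) to 609 ± 19.8 CPM, and Bmi1, a Polycomb protein of self-renewing cells, from 49.4 ± 4.14 to 125 ± 4.29 CPM. Prom1, which encodes the surface protein CD133, fell from 158 ± 17.5 to 27.6 ± 7.04 CPM, and the RNA-binding protein gene Msi1 from 172 ± 8.72 to 22.1 ± 8.79 CPM. Sox2 had a log2 fold change of -0.31 ± 0.12 (edgeR adjusted p = 0.147) and Nes one of -0.47 ± 0.17 (edgeR adjusted p = 0.135). The list was called without TRP 1, with a median of -0.67 (camera adjusted p = 0.0358), and without TRP 2, with a median of -2.03 (camera adjusted p = 0.000618).

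Proneural glioblastoma genes were lower in TRP, with 3 of 12 fallen and 9 not passing (3 over the list alone), a median of -1.68 and a camera adjusted p of 0.0415, against an adjusted p of 0.59 with an estimated correlation. The Notch ligand gene Dll3 had a log2 fold change of -7.87 ± 0.76, and Pdgfra, a growth factor receptor gene of oligodendrocyte precursors, fell from 185 ± 23.5 CPM (SD, n = 2) to 12.3 ± 5.46 CPM. The call on this list ended without TRP 1 (camera adjusted p = 0.123), with upper quartile factors or library size alone, and with fry, and the median was -0.88 without TRP 1 and -4.29 without TRP 2. The mesenchymal glioblastoma genes were not called, with a median of 0.45 and a camera adjusted p of 0.257, and the sign of the median rested on TRP 1, with -0.428 without it and 0.721 without TRP 2. Cd44 and the inflammatory caspase gene Casp1 rose, Icam1 and Stat3 fell, and 11 of 15 did not pass (5 rose and 3 fell over the list alone).

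Cell cycle genes were higher in TRP. Of 28 E2F and G1/S genes 23 rose and 5 did not pass (27 over the list alone), with a median log2 fold change of 1.24 and a camera adjusted p of 2.75e-10, against an adjusted p of 0.346 with an estimated correlation. The transcription factor gene E2f1 rose from 26.5 ± 0.151 CPM (SD, n = 2) to 86.8 ± 0.979 CPM, and Uhrf1, which acts in the maintenance of DNA methylation, from 110.2 ± 4.004 to 269.5 ± 6.66 CPM. Of 21 G2/M and mitosis genes 16 rose and 5 did not pass (20 over the list alone), with a median of 0.86 (camera adjusted p = 8.79e-08, adjusted p = 0.346 with an estimated correlation). The spindle checkpoint kinase gene Bub1 had a log2 fold change of 1.23 ± 0.10 and the kinetochore motor gene Cenpe one of 1.09 ± 0.10. In both lists every tested member had a positive log2 fold change.

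RAS-MAPK output and feedback genes were higher in TRP as a list. Of 19 members 6 rose, 0 fell and 13 did not pass (8 rose over the list alone), with a median log2 fold change of 1.08 and a camera adjusted p of 0.00119, against an adjusted p of 0.425 with an estimated correlation and 0.0523 with fry. The AP-1 subunit gene Fosl1 rose from 7.97 ± 0.00406 CPM (SD, n = 2) to 38.1 ± 10.6 CPM and Phlda1 from 11.4 ± 1.22 to 80.8 ± 33.1 CPM. FOXO target genes were not called by camera, with a median of -0.44 (-0.0519 without TRP 1) and an adjusted p of 0.322, but by fry, with an adjusted p of 0.0213. Of 17 members 3 fell and 14 did not pass (2 falls over the list alone). The transcription factor gene Klf15 fell from 23.4 ± 1.24 to 2.28 ± 0.388 CPM and the ubiquitin ligase gene Fbxo32 from 47.5 ± 3.07 to 4.23 ± 1.42 CPM. For p53 target genes, 3 of 21 fell and 18 did not pass (2 falls over the list alone), with a median of -0.72 and a camera adjusted p of 0.0552. Btg2, an antiproliferative gene, fell from 81.9 ± 4.74 to 12.3 ± 4.48 CPM, and Zmat3 had a log2 fold change of -0.67 ± 0.10. That list was called without TRP 2 (camera adjusted p = 0.0017).

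DNA repair lists, chosen because the title names radiation and temozolomide, were higher in TRP. Cell cycle genes rose too, with a median of 1.24 for E2F and G1/S genes. Whether the repair lists moved apart from the cell cycle was not tested. Of 21 homologous recombination and Fanconi genes 14 rose and 7 did not pass (20 over the list alone), with a median log2 fold change of 1.12 and a camera adjusted p of 1.01e-07, against an adjusted p of 0.346 with an estimated correlation. Bard1, the partner of Brca1, rose from 21.7 ± 0.618 CPM (SD, n = 2) to 59.2 ± 4.23 CPM and the Fanconi core gene Fanca from 31.0 ± 1.12 to 73.0 ± 0.536 CPM. Of 20 alkylation, mismatch and base excision repair genes 5 rose, 1 fell and 14 did not pass (7 and 1 over the list alone), with a median of 0.51 (camera adjusted p = 0.00824, adjusted p = 0.346 with an estimated correlation). The DNA ligase gene Lig1 had a log2 fold change of 0.94 ± 0.09 and the uracil glycosylase gene Ung one of 1.15 ± 0.15, whereas Mpg, which removes alkylated purines, fell from 7.52 ± 0.515 to 1.05 ± 0.121 CPM. Mgmt, which removes alkyl groups from guanine, had 296 and 292 counts in AC, 422 in TRP 1 and 107 in TRP 2. Scaled to library size, Mgmt stood at 7.81 and 8.25 CPM in AC, 7.82 in TRP 1 and 1.64 in TRP 2. Its log2 fold change was -0.77 ± 0.84 (edgeR adjusted p = 0.538). Of 11 non-homologous end joining genes 3 rose (also 3 over the list alone) and 8 did not pass, with a median of 0.54 (camera adjusted p = 0.0178, adjusted p = 0.346 with an estimated correlation), among them Xrcc6 at 1.55 ± 0.28 and Paxip1 at 0.76 ± 0.13. The end joining median was 0.287 without TRP 1 and 0.646 without TRP 2. The call on that list ended without TRP 1 and with DESeq2. The calls of Xrcc6 and Paxip1 ended with library size alone and with the stricter filter.

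Of 17 glycolysis genes 5 rose, 2 fell and 10 did not pass (9 and 2 over the list alone), with a median of 0.62, a mean of 0.17 and a camera adjusted p of 0.0415, against an adjusted p of 0.346 with an estimated correlation. Tpi1 rose from 192 ± 16.5 CPM (SD, n = 2) to 533 ± 57.0 CPM and Pfkl from 59.9 ± 2.08 to 169.97 ± 29.1 CPM, while the lactate transporter gene Slc16a3 fell by 3.60 and Pfkfb3 fell by 3.31 on the log2 scale. Of 20 cholesterol and fatty acid synthesis genes 2 rose, Ldlr and Fdps, and 18 did not pass (2 over the list alone), with a median of 0.31 (camera adjusted p = 0.0415, adjusted p = 0.518 with an estimated correlation). Ldlr, the receptor for low-density lipoprotein, had a log2 fold change of 1.38 ± 0.15 and Fdps one of 1.07 ± 0.16. The glycolysis call ended without AC 1 (camera adjusted p = 0.0564), TRP 1 (0.0643) or TRP 2 (0.077), and the cholesterol call without AC 1 (0.0708) or TRP 2 (0.0796). Both also ended with DESeq2 and with the stricter filter, and the cholesterol call with upper quartile factors, library size alone and fry as well (fry adjusted p = 0.0523). The call of Pfkfb3 ended without a filter and with the stricter one.

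Hox genes of the A cluster, which set position along the body axis, were detected in TRP and near 0 counts in AC. Of the 39 listed Hox genes, which cover the A, B, C and D clusters, 8 passed the filter and 31 were not tested. The 8 rose (also 8 over the list alone), but with near 0 counts in AC they passed the filter only through their counts in TRP, so the filter itself favoured rises. Without the filter, 23 had a count in at least 1 library, of which 8 rose, 0 fell and 15 did not pass, with a median log2 fold change of 4.57 fitted and a camera adjusted p of 0.000215. With the filter, the median was 8.08 fitted and 5.70 with bounds (camera adjusted p = 3.52e-07, adjusted p = 0.346 with an estimated correlation). Hoxa3 had 2 counts in each AC library against 450 and 707 in TRP, and Hoxa2 had 3 in each against 101 and 138. Hoxa5 was at least 214-fold higher, with 0 counts in both AC libraries.

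The remaining lists were not called by camera. Extracellular matrix and mesenchymal genes had a median of -0.20 (camera adjusted p = 0.293), with 1 of 25 rising, 3 falling and 21 not passing, the same numbers of rises and falls as over the list alone. Twist1, a transcription factor of mesenchymal cells, rose from 5.39 ± 3.37 CPM (SD, n = 2) to 94.9 ± 30.9 CPM, the gelatinase gene Mmp2 fell from 66.8 ± 10.4 to 2.16 ± 0.252 CPM, and Snai1 fell by 6.55 on the log2 scale. Reactive astrocyte genes had a median of -0.55 (camera adjusted p = 0.213), with 2 of 23 rising (Fkbp5 and Cp) and 4 falling, among them Serping1 and Cd14, or 2 and 7 over the list alone. Class I antigen presentation genes had a median of -0.87 (camera adjusted p = 0.152, but 0.0278 with fry), with H2-T23 rising and H2-K1 falling among 12, and 0 rising and 1 falling over the list alone. H2-T23 lost its call under each other scaling and filter tried. Of 20 interferon response genes 0 passed by edgeR, overall or over the list alone, with a median of 0.89 (camera adjusted p = 0.152), while 2 had an unadjusted p under 0.05, DESeq2 called 3 and limma voom 0. Xaf1 had a log2 fold change of 2.33 and Bst2 one of 1.87. Of 14 immediate early and heat shock genes 0 passed by edgeR, overall or over the list alone, with a median of -0.21 (camera adjusted p = 0.55). At an unadjusted p under 0.05 there were 5, DESeq2 called 5 and limma voom 3, and Nr4a1 and Fos had log2 fold changes of -3.26 and -3.48. Without TRP 2 the interferon list was called (camera adjusted p = 0.000372), while without TRP 1 its median was -0.106. Without TRP 1 the class I list (camera adjusted p = 0.0403) and the reactive astrocyte list (0.0175, median -1.78) were called, while without TRP 2 the reactive astrocyte median was 0.277. The median of extracellular matrix and mesenchymal genes was -1.84 without TRP 1 and -0.361 without TRP 2.

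The TRP libraries differed from each other more than the AC libraries did. At 20 CPM or more in 1 library of the pair, 232 genes differed at least 8-fold between TRP 1 and TRP 2, 100 higher in TRP 1 and 132 higher in TRP 2, against 0 genes between AC 1 and AC 2. The biological coefficient of variation was 0.597 in TRP and 0.0909 in AC. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.928 between the TRP libraries, 0.989 between the AC libraries and between 0.800 and 0.846 across the groups. Chi-square per degree of freedom was 12.5 within AC and 416 within TRP, so no library was a repeat of another within sampling noise. The first principal component held 81.0% of the variance and separated TRP from AC, and the second, with 17.3%, separated TRP 1 from TRP 2. Among sex-linked genes, Ddx3y, Uty and Eif2s3y had at least 1436 counts in every library, whereas Kdm5d had 1934, 1701 and 2308 counts in AC 1, AC 2 and TRP 1 and 1 count in TRP 2. Xist had 33 and 120 counts in AC and 6 and 2 in TRP.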

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

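Limma voom with a variance factor for each group was chosen after the data were seen, and all other alternatives before. Against 1371 genes higher and 1977 lower in TRP, DESeq2 gave 2832 and 3471 (3326 of its calls shared with edgeR's 3348), and 589 and 1971 beyond 1.5-fold against 348 and 1150. Upper quartile factors gave 904 higher genes and library size alone 901. The stricter filter of 5 CPM in 2 libraries, which tests fewer genes, gave 1224 lower genes, and 217 higher and 652 lower beyond 1.5-fold. Voom with a variance factor per group gave 231 higher and 538 lower genes beyond 1.5-fold and shared 2717 calls with edgeR. At an adjusted p under 0.01, edgeR called 0 genes in each direction, with and without the 1.5-fold limit, limma voom called 0 and DESeq2 4742, with 6726 edgeR genes at an unadjusted p under 0.05. The causes of these shifts were not tested, apart from the number of genes under the filter.

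Leaving out a library leaves its group with 1, which is then assumed to vary like the other group. Over the 4 libraries left out in turn, the number of higher genes ranged from 0 to 5429 and that of lower genes from 0 to 6241. Beyond 1.5-fold the ranges were 0 to 2695 and 0 to 4439. The 0 calls came without AC 1 or AC 2, where the spread rests on the TRP libraries alone, with 2251 and 2412 genes at an unadjusted p under 0.05, 0 calls by limma voom, and 1203 and 1367 by DESeq2. Cdkn2a ranged from -4.84 without TRP 1, a reversal, to 5.68 without TRP 2. Of results that did not pass in the main test, 5 others changed sign when a library was left out. Pten ranged from -0.122 (without TRP 2) to 0.0977 (without TRP 1), with 0.0422 without AC 1, Rb1 from -0.639 (without TRP 2) to 0.146 (without TRP 1), the interferon list from -0.106 (without TRP 1) to 1.26, the mesenchymal glioblastoma list from -0.428 (without TRP 1) to 0.721 and the reactive astrocyte list from -1.78 to 0.277 (without TRP 2), which was also above 0 with the stricter filter (0.0782), where the cause was not tested. The stem cell list ranged from -2.03 (without TRP 2) to -0.67 (without TRP 1) and passed the camera threshold in both of these. It also passed without a filter (-1.54), with the stricter filter (-1.28) and with voom per group (-1.70), where the cause was not tested.

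The replicate numbers were taken as names only, since same-numbered libraries did not deviate together (correlation of deviations -0.0485 across genes). With a replicate block, which leaves fewer residual degrees of freedom, edgeR called 0 genes higher and 0 lower, and 0 and 0 beyond 1.5-fold, with 4905 genes at an unadjusted p under 0.05, 790 calls by limma voom and 3760 by DESeq2. The stem cell list passed under the block, at -1.72.

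With an estimated correlation, camera called 0 of the 26 lists, against 17 with the preset one and 16 with fry. That form of camera rests on the 2 residual degrees of freedom, and its power was not tested. Its lack of calls may reflect low power or members that vary together, and does not decide whether a list moved. The medians, which this choice does not move, were -3.26 for astrocyte markers, 1.24 for E2F, 0.86 for G2/M, 1.08 for RAS-MAPK, 1.12 for homologous recombination and 0.51 for alkylation repair genes. With fry the RAS-MAPK list (1.08) no longer passed and the FOXO list (-0.44) did. Over all alternatives, the 18 secondary lists kept their direction and side of the threshold in 231 comparisons, lost a call in 43, gained one in 10 and changed sign in 4. For the 95 values of named genes these numbers were 918, 269, 39 and 4. For genes without counts in a group, depth limits the fold change to a bound.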

Other observations

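Genes of the amino acid stress response, which the transcription factor ATF4 drives, were higher in TRP. The list was made after Trib3 and Chac1, both known ATF4 targets, had been seen among the large rises, and it leaves both out. The value of 1 member, Wars, had been seen before. Of 24 further genes 14 rose, 0 fell and 10 did not pass by edgeR (17 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.94. The camera p was 7e-07, and 0.165 with an estimated correlation. Mthfd2, a mitochondrial folate enzyme, rose from 21.9 ± 2.997 CPM (SD, n = 2) to 146 ± 37.4 CPM, the serine enzyme gene Shmt2 from 71.1 ± 4.85 to 280.2 ± 64.7 CPM, and the amino acid transporter gene Slc7a5 from 123 ± 21.4 to 468 ± 38.5 CPM. A rise of this response as a set remains a hypothesis, because it was found and tested on the same libraries.

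Imprinted genes were lower in TRP. The list was made after Dlk1, Meg3 and Rian had been seen near 0 counts in TRP, and it leaves them out, although Mirg belongs to the same cluster. Of 24 tested genes 8 fell, 0 rose and 16 did not pass (13 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -1.64, which was the same with bounds for genes without counts. The camera p was 0.0002, and 0.113 with an estimated correlation. Igf2, a growth factor gene, had 2056 and 5475 counts in AC and 5 and 7 in TRP, and the signalling adaptor gene Grb10 had 3963 and 5106 against 2 and 5. Nnat fell from 157 ± 1.98 CPM (SD, n = 2) to 0.842 ± 0.196 CPM and the cell cycle inhibitor gene Cdkn1c from 8.51 ± 0.505 to 0.0862 ± 0.0352 CPM. The 2 that rose over the list alone were Igf2r, with a log2 fold change of 0.95, and Airn, with one of 1.24. Peg10, which did not pass, had 13258 and 10802 counts in AC, 145176 in TRP 1 and 14917 in TRP 2. Scaled to library size, Peg10 stood at 350 and 305 CPM in AC, 2689 in TRP 1 and 229 in TRP 2. A fall of imprinted genes as a set remains a hypothesis, because it was found and tested on the same libraries. Pericyte and meningeal fibroblast markers fell as well (median -3.82). Whether the make-up of the cultures plays a part in the fall of imprinted genes was not tested.

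Of the tests on the 3 patterns that follow, those on passages, AC RNA in TRP 2 and a wrong label were chosen after the values had been seen, and those on depth and on GC content before.

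Markers of astrocytes, microglia and other brain cell types were lower in TRP together, and whether the make-up of the cultures, the state of the cells or both differ was not tested. For the astrocyte markers, as for every other difference between TRP and AC, the number of passages cannot be told apart from the genotype. The reason is that 0 libraries of one group had a passage number of the other.

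TRP 1 and TRP 2 lay further apart than AC 1 and AC 2. With all 4 libraries thinned to 34097156 counts, the SD of log2 ratios between the TRP libraries was 3.39 times that between the AC libraries (1.36 against 0.403), which argues against depth. RNA of AC cells in TRP 2 would need a share of at least 25.4% to supply its Kcnj10, yet 26 of 930 genes at 200 CPM or more in AC stood in TRP 2 below 10% of that share, Ntrk2 at 0.0378% of its AC level. TRP 2 is unlikely to be an AC library, since its correlation with TRP 1 across genes exceeded its highest with an AC library by 0.0818. A difference between the cultures, such as passage within the range of the label or separate lines, stays open as untested.

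Both TRP libraries showed shifts in the medians of chromosomes. Whether a shift ran along a whole chromosome or a part of it was not tested. Over 10957 genes at 5 CPM or more that were placed on the GRCm38.p6 annotation, the median log2 ratio to AC, relative to all genes, was 0.39 on chromosome 16, 0.27 on X and 0.24 on chromosome 15 in TRP 1, and 0.47 on chromosome 12, 0.32 on chromosome 19 and 0.29 on chromosome 10 in TRP 2. The lowest medians were -0.198 on chromosome 7, -0.190 on 18 and -0.188 on 9 in TRP 1, and -0.112 on X and -0.102 on 18 in TRP 2. Between the AC libraries the medians stayed within -0.013 and 0.0148. After a fit on GC content and transcript length (99.8% of these genes had values), the SD of chromosome medians was 0.154 in TRP 1 and 0.153 in TRP 2. Both lay above the highest of 1000 random assignments of genes to chromosomes (0.0697 and 0.058), which argues against these biases. Random assignment is a narrow reference, however. Between the AC libraries the SD after the fit was 0.00742, and only 17 of 1000 assignments were as large. A candidate explanation is a gain or loss of chromosomes in culture, and DNA copy number was not analysed here.

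In TRP 2, Cdkn2a and its neighbour Cdkn2b had 13 and 14 counts, while the adjacent Mtap had 17241. In TRP 1 these genes had 15949, 3130 and 17093 counts, and in the AC libraries Mtap had 2630 and 2781. Scaled to library size, Mtap stood at 69.4 and 78.6 CPM in AC, 317 in TRP 1 and 264 in TRP 2. Kdm5d had 1 count in TRP 2, where the Y-linked genes Ddx3y, Uty and Eif2s3y had 4384, 1574 and 2683. These genes were chosen after their values were seen.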
